A study of Mus musculus with 23 samples.

How the data were processed

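Gene expression was measured by RNA sequencing of liver from C57BL/6J mice in 23 libraries of 6 groups: vehicle of batch 1, LBP (batch 1), vehicle of batch 2, EPDR1, FCN2 and FSTL3 (batch 2). Per the labels, 800 ng of total RNA went into each library (KAPA Hyper-prep), which was sequenced paired-end on a HiSeq 4000. The deposited values are raw read counts per gene. Reads were aligned to GRCm38 with STAR 2.6.0c, per the submitters' processing notes, and counted over exons with featureCounts 1.6.3 and Ensembl release 95, per the file headers. The recorded command sets no strand, pairing or multi-mapping option, so by the program's defaults reads were counted without strand, each read singly and only where mapped uniquely. The counts were used as deposited. The file holds 54838 genes, of which 54723 IDs were matched to symbols and 54809 were found in GENCODE M21, 54123 of them with identical coordinates. All count columns were mapped to samples, and each sample's group was taken from its label.

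Total counts per library ran from 773499 to 21892416 (median 3712802). Genes were kept by edgeR's filterByExpr (11969 genes), scaled by TMM and fitted with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood, robust dispersion) with all 23 libraries and a mean per group. Each protein was compared with the vehicle of its batch, the proteins of batch 2 with each other, the LBP response with each response of batch 2 as a difference of differences, and the vehicles with each other. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The common dispersion was 0.0774, and 0.0298 without LBP replicate 2 (12244 genes). On data simulated from these libraries, with 200 genes changed per comparison, edgeR called 85.1% (EPDR1), 82.4% (FCN2), 88.4% (FSTL3) and 70.7% (LBP) of genes changed 4-fold, 40.5%, 30.8%, 32.8% and 22.2% of those changed 2-fold, and 3, 5, 6 and 4 unchanged genes. Levels in CPM use the TMM-scaled library size. A fold against a group with no reads was computed against a floor of 3 counts over the group, and one against 1 to 3 reads was given as a ratio of pooled counts with its Poisson interval.

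Before the data were examined, 48 gene lists were written down, covering metabolism, immunity, signalling, stress, the circadian clock and markers of other cell types, and the comparisons, the tests, the other settings to be tried and the rule for naming genes were fixed. Lists with at least 5 measured members (41) were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, and again with the correlation estimated per list. Lists with too few measured members were those for female-biased genes (4), monocytes (2), neutrophils (3), T and NK cells (0), B cells (3), adipocytes (1) and skeletal muscle (3). The genes named are, for each protein, the 10 highest and 10 lowest called genes with a mean of at least 1 CPM, a symbol that is not a predicted name and no overlap between the groups; where fewer than 10 passed, those with the smallest unadjusted p; the 4 members with the smallest p of each called list; 2 members of each of 6 metabolic and signalling lists fixed beforehand; and the mouse genes of the proteins. Other comparisons name 5 and 5. Some genes that this rule selects are not reported here. Shares of counts per library were compared by exact 2-sided permutation tests, adjusted over 40 tests. Correlations between libraries used 11116 genes with a mean over 2 CPM and a pseudocount of 1.

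The other settings chosen then were DESeq2 1.42.0 and limma-voom in place of edgeR, DESeq2 size factors, no filter, a stricter filter, only the libraries compared, pooled vehicles, a block for the replicate number, fry, split vehicles and leaving out each library. After the data were seen, settings without LBP replicate 2, without the FSTL3 libraries, with each library's GC trend removed, with protein-coding nuclear genes alone and with the vehicle of batch 1 as the control of FSTL3 were added. No library was left out of the main comparisons.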

Results

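Liver RNA was sequenced from C57BL/6J mice, a common inbred laboratory strain, that had received vehicle or a recombinant secreted protein. The 4 proteins were EPDR1 (ependymin-related protein 1), FCN2 (ficolin-2, a lectin of the complement system), FSTL3 (follistatin-like 3, which binds activins) or LBP (lipopolysaccharide-binding protein). The proteins were chosen as possible endocrine factors in a study of cardiometabolic and coronary artery disease. The question asked of each was which liver genes differed after it was injected. Each mouse received 1 µg of protein per g of body weight in 3 injections spaced by 1 day. EPDR1, FCN2 and FSTL3 were given in batch 2 and LBP in batch 1, each batch with vehicle samples of its own. There were 23 libraries: 4 each of EPDR1, FCN2 and FSTL3, 3 of LBP (replicates 2, 3 and 4) and 4 of vehicle in each batch. The labels number the samples of a group but do not say that each came from a separate animal, so the p-values measure the spread between these samples, which may in part be technical. The counts of replicates differed by more than sampling noise in all 33 pairs (chi-square per degree of freedom 2.47 or more). Throughout, log2 fold changes are given ± SE and levels as mean ± SD in CPM (counts scaled to library size), with n of 4 per group except for the 3 LBP libraries.

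Total gene counts ran from 3005739 to 4180013 in the EPDR1 libraries, 2735871 to 7060707 in FCN2, 9298871 to 10930800 in FSTL3 and 1463037 to 3712802 in LBP. They ran from 773499 to 8286793 in the vehicle of batch 1 and 2517701 to 21892416 in the vehicle of batch 2. The FSTL3 libraries had a composition of their own. Small structural RNAs such as 7SK made up 0.725% ± 0.0394 of their counts, against 0.00675% ± 0.000957 in the vehicle of batch 2 (2-sided exact permutation p = 0.0286, the smallest that 4 against 4 allow; 0.0952 adjusted over 40 such tests). Long noncoding RNAs made up 2.22% ± 0.25 against 0.636% ± 0.09 (the same exact p), and protein-coding mitochondrial genes 1.97% to 2.13% against 7.36% to 11.8%. LBP replicate 2 also stood apart. Albumin, the main secreted product of hepatocytes, took 0.211% of its counts against 5.26% to 8.36% in the other 22 libraries. Its expression profile correlated with those of its own group at a median r across genes of 0.627. Pancreatic acinar genes took 0.125% of counts in LBP replicate 2 and 0.081% in LBP replicate 4, but 0.002% in LBP replicate 3 and at most 0.012% in the vehicle of batch 1. Because all libraries share the estimate of the spread, the main counts are also given without LBP replicate 2.

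**Figure D1:**
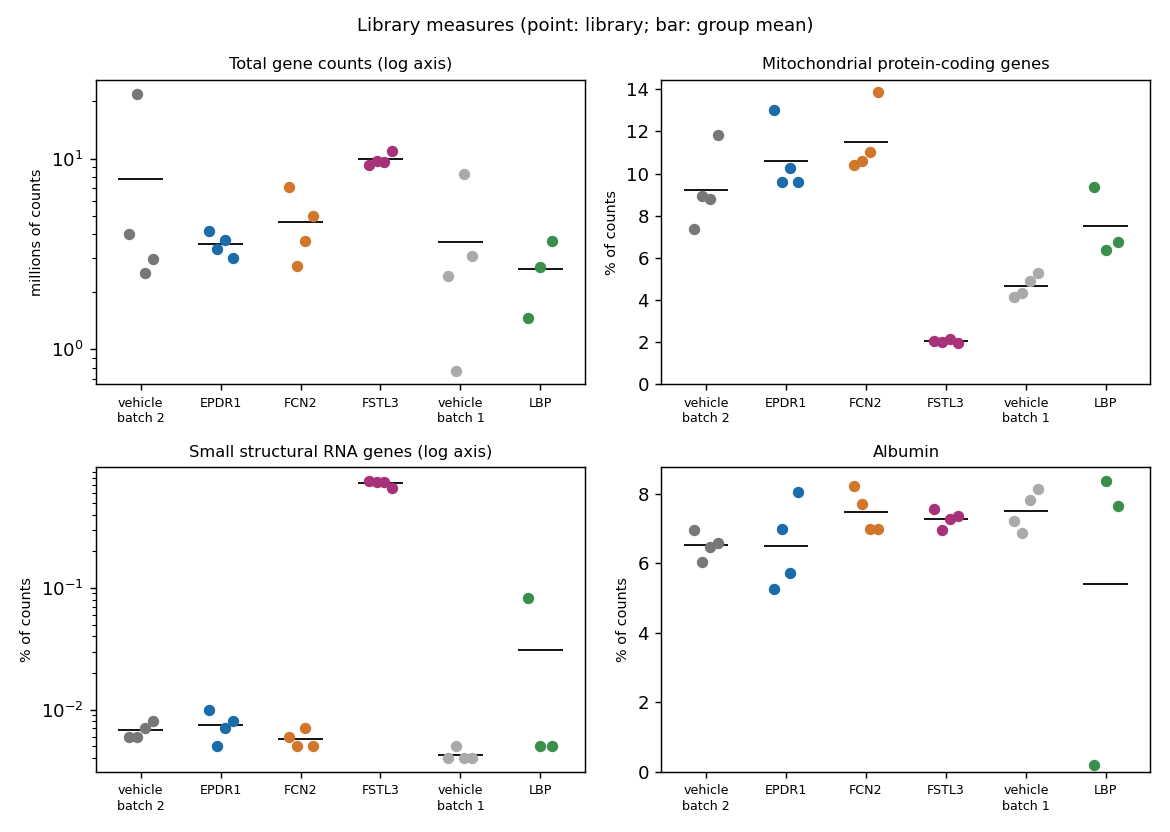
Composition of the 23 libraries by group: total gene counts (log axis), percent of counts in protein-coding mitochondrial genes, percent in small structural RNA genes (log axis) and percent in albumin; each point is a library and each bar a group mean. The 4 FSTL3 libraries lie between 0.667% and 0.753% for small structural RNA, above every other library, and LBP replicate 2 has the lowest albumin share, 0.211%.

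The mouse genes of the injected proteins were read in every library. Lbp (ENSMUSG00000016024, GRCm38 chromosome 2, 158306493 to 158332852) had 37 to 2408 counts and Fcna (ENSMUSG00000026938, chromosome 2, 25624666 to 25628030), a ficolin gene of macrophages, had 29 to 446. Epdr1 reached 5 counts at most and was at 0 in 7 libraries. Fstl3 had 1 count in 1 library, and Fcnb was at 0 in all 23, below a floor of 3 counts over all libraries (0.0238 CPM). Those low genes could not be tested at this depth. Against vehicle, Lbp was lower after FSTL3 (69.1 ± 9.5 against 125 ± 30.3 CPM; log2 -0.85 ± 0.33, edgeR adjusted p = 0.0414), a call that was lost on leaving out any single library of either group except vehicle replicate 4. Fcna did not pass after FSTL3 (log2 -0.85 ± 0.39, edgeR adjusted p = 0.0895) or FCN2 (14.4 ± 3.71 against 26.2 ± 5.06 CPM; log2 -0.85 ± 0.41, edgeR adjusted p = 0.289). It passed in both without LBP replicate 2 (edgeR adjusted p = 0.000382 and 0.00674).

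After FSTL3, compared with the vehicle of its batch, 4695 of 11969 genes differed, 2776 higher and 1919 lower. The FSTL3 libraries also had the RNA composition given above and the clock gene difference given below. For none of these genes can an effect of the protein be told apart from whatever else set those libraries apart. The highest were noncoding RNAs that are made without a poly(A) tail. Rn7sk, the 7SK RNA that holds back transcription elongation (ENSMUSG00000065037, chromosome 9, 78175303 to 78175633), rose from 6.78 ± 1.19 to 5488 ± 220 CPM (log2 9.69 ± 0.49). Others had 1 to 3 counts in all over the vehicle libraries, so the ratio of pooled counts is given with its 95% counting interval. Rpph1, the RNA of RNase P, was 1521-fold higher (273 to 60087) and Snord17 862-fold (238 to 7118). Scarna6 was 713-fold higher (128 to 28205), Snora23 323-fold (89.2 to 2672) and Vaultrc5 153-fold (52.2 to 744). Scarna13 and Snora78, at 0 in every vehicle library, were at least 159-fold and 71.4-fold higher. Lrrtm2 (124-fold, 34.0 to 1025) and Gpr21 (96.5-fold, 17 to 3837) complete the highest 10; both lie inside longer genes, Ctnna1 and Rabgap1, and the reads were counted without strand. The lowest were mostly secreted liver products. They were the serum amyloid A genes Saa1 (14.7 ± 3.99 against 1465 ± 1828 CPM; log2 -6.64 ± 1.21) and Saa2 (-7.28 ± 1.46), and the major urinary protein genes Mup19 (-7.07 ± 0.62), Mup8 (-6.07 ± 0.57), Mup4 (-5.00 ± 0.52) and Mup10 (at 0 after FSTL3, at least 79-fold lower). The others were the siderophore-binding lipocalin Lcn2 (-5.41 ± 1.07), Serpina3c (-5.10 ± 0.58), Vmn1r13 (119-fold lower, 20.8 to 4766, from 1 count in all after FSTL3) and the Kupffer cell receptor Marco (-4.94 ± 0.91). Mup, Saa and Serpina3 genes have near-identical neighbours that share reads, so values of single members are uncertain. The vehicle mean of Saa1 owed much to vehicle replicate 3 (4205 CPM); without it Saa1 changed by -5.23 and Lcn2 by -3.95. By edgeR, 6950 genes were called without LBP replicate 2, 4691 of them in both counts and in the same direction. With the vehicle of batch 1 as the control, 3817 were called, 2649 of them in the same direction, and 10 of the genes named here took the opposite sign.

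**Figure D2:**
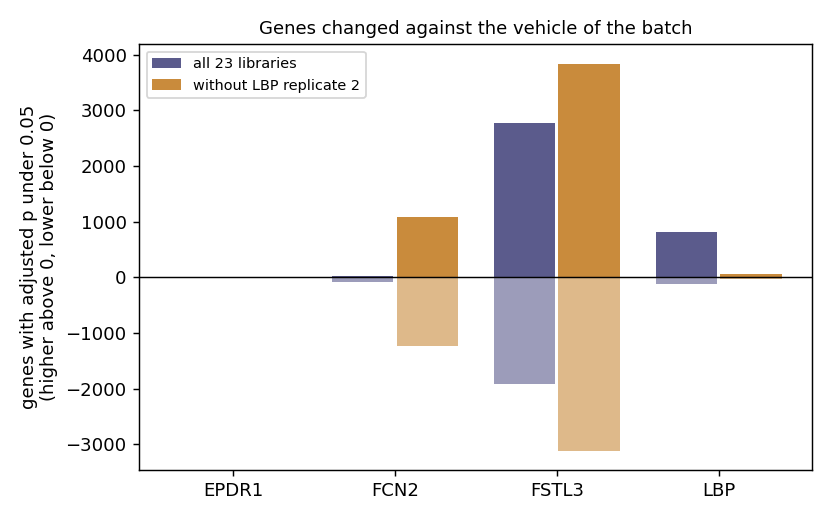
Genes with edgeR adjusted p under 0.05, higher and lower than vehicle, for each protein with all 23 libraries and without LBP replicate 2. FSTL3 has the most genes with either set of libraries (4695 and 6950) and EPDR1 has none.

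Genes of circadian rhythm split by their place in the clock. Of the 12 genes of the Per and Dbp arm, which peak around the end of the light phase, 9 rose after FSTL3 (9 adjusted over the list alone; camera adjusted p = 0.000413, but adjusted p = 0.485 with an estimated correlation). Among them were Per3 (log2 3.48 ± 0.33), Ciart (3.91 ± 0.62), Per1 (2.12 ± 0.31) and Tef (1.87 ± 0.20). Of the 5 measured genes of the Bmal1 arm, in the opposite phase, 4 fell (4 adjusted over the list alone; camera adjusted p = 0.00324, but adjusted p = 0.357 with an estimated correlation). These were Arntl (-2.89 ± 0.33; ENSMUSG00000055116, chromosome 7, 113207465 to 113314126), Npas2 (-3.23 ± 0.48), Nfil3 (-2.05 ± 0.25) and Cry1 (-0.80 ± 0.27). The Cry1 call was lost without FSTL3 replicate 4 or vehicle replicate 1 or 2. Per library, the median of the Per and Dbp arm minus that of the Bmal1 arm was 3.69 ± 0.234 on the log2 scale in FSTL3 and 0.0055 ± 0.495 in vehicle (2-sided exact permutation p = 0.0286; 0.0952 adjusted). The vehicle libraries of batch 1, which received no protein, had 3.02 ± 0.323. With those as the control, Arntl (0.43), Npas2 (1.56), Ciart (-0.04) and Per1 (-0.65) had the opposite sign and did not pass, though Per1 passed in that direction without LBP replicate 2.

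**Figure D3:**
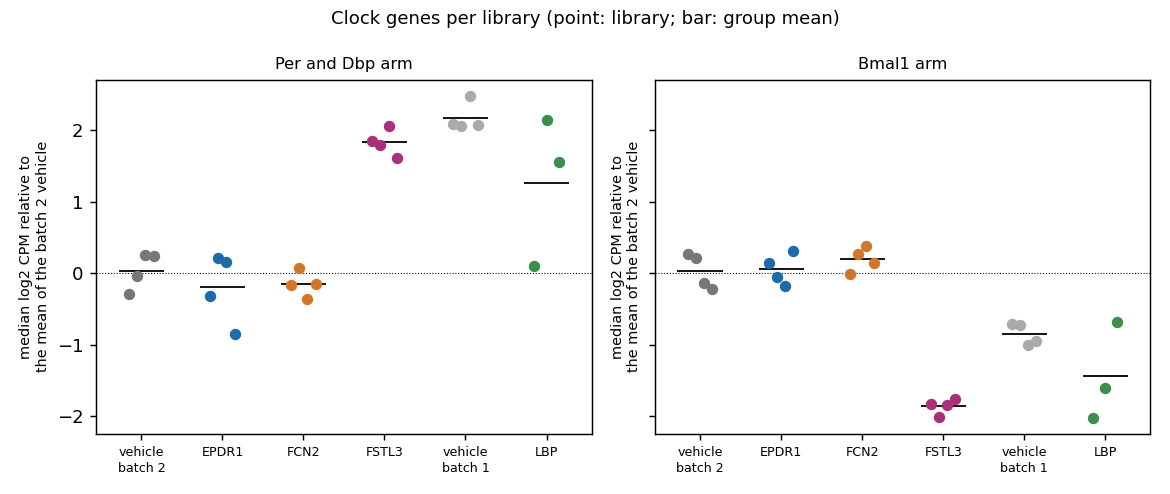
Median log2 CPM of the Per and Dbp arm (left) and of the Bmal1 arm (right) by group, relative to the mean of the vehicle libraries of batch 2. Each point is a library and each bar a group mean. The FSTL3 libraries and the libraries of batch 1 other than LBP replicate 2 have the Per and Dbp arm high and the Bmal1 arm low. LBP replicate 2 has the Bmal1 arm low (-2.02) but the Per and Dbp arm near vehicle of batch 2 (0.093). The difference of the arms is 3.37 to 3.91 in FSTL3 and 2.78 to 3.48 in the vehicle of batch 1.

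Genes of sterol and lipid metabolism moved in different directions after FSTL3. Of 25 cholesterol synthesis genes, 10 fell (10 adjusted over the list alone; camera adjusted p = 0.00682, but adjusted p = 0.697 with an estimated correlation). On leaving out LBP replicate 2, 14 were lower and 1 higher. Genes that fell with all libraries included Hmgcs1 (log2 -1.69 ± 0.33), which makes HMG-CoA, Sqle (-1.58 ± 0.31), Fdft1 (-1.46 ± 0.28) and Nsdhl (-1.70 ± 0.37). Fatty acid synthesis as a list did not pass (7 of 19 higher and 1 lower, the same adjusted over the list alone; camera adjusted p = 0.425). Srebf1, its main transcription factor, rose from 34.3 ± 5.1 to 121 ± 13.1 CPM (log2 1.82 ± 0.31) and Acaca, acetyl-CoA carboxylase, rose by 1.58 ± 0.18. Cyp7a1, the rate-limiting enzyme of bile acid synthesis (ENSMUSG00000028240, chromosome 4, 6265612 to 6275633), rose from 51.9 ± 12.1 to 294 ± 108 CPM (log2 2.51 ± 0.50), and Baat, which conjugates bile acids, fell by 0.97. The bile acid synthesis list of 8 did not pass (camera adjusted p = 0.636). Ppara (1.96 ± 0.29) and Acot3 (3.07 ± 0.70) rose within a list of PPAR-alpha targets and fatty acid oxidation that did not pass (2 of 26 higher and 2 lower; camera adjusted p = 0.636). The mean of that list (0.076) was positive, its median (-0.095) and its test negative. Male-biased liver genes fell in 9 of 12 (10 adjusted over the list alone; camera adjusted p = 0.0025, but adjusted p = 0.649 with an estimated correlation). Examples were Mup20 (-1.65 ± 0.36), Mup21 (-1.82 ± 0.33), Ugt2b38 (-3.04 ± 0.62) and the fatty acid elongase Elovl3 (-1.38 ± 0.25). These lists lay beside the clock difference above. Against the vehicle of batch 1, whose clock genes were closer to those of FSTL3, Srebf1 (-0.14), Baat (0.03), Acot3 (-0.31) and Elovl3 (0.34) had the opposite sign and did not pass.

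Lists of plasma protein and immune genes did not all pass after FSTL3. Coagulation (2 of 18 lower; camera adjusted p = 0.336), NF-kB and cytokine genes (2 of 12 lower; camera adjusted p = 0.168) and antigen presentation (2 of 15 higher and 3 lower; camera adjusted p = 0.636) were not called. Without LBP replicate 2 these had 2 higher and 8 lower, 5 lower, and 2 higher and 5 lower, and again were not called (camera adjusted p = 0.124, 0.252 and 0.615). Acute phase genes fell in 19 of 27 (21 adjusted over the list alone; camera adjusted p = 4.9e-05, but adjusted p = 0.649 with an estimated correlation). Orm2 stood at log2 -3.84 ± 0.68, Apcs, serum amyloid P, at -2.22 ± 0.39 and Saa4 at -2.15 ± 0.38. Complement genes fell in 6 of 20 (5 adjusted over the list alone; camera adjusted p = 0.0432, but adjusted p = 0.665 with an estimated correlation). Those included C8b (-1.18 ± 0.25), C9 (-1.36 ± 0.38) and Mbl1 (-1.17 ± 0.32), and 15 passed without LBP replicate 2. Interferon response genes fell in 9 of 33 (8 adjusted over the list alone; camera adjusted p = 0.00692, but adjusted p = 0.737 with an estimated correlation), such as Zbp1 (-2.35 ± 0.38) and Isg15 (-2.18 ± 0.49); 12 of 34 were lower and 1 higher without LBP replicate 2. Kupffer cell markers fell in 5 of 12 (6 adjusted over the list alone; camera adjusted p = 0.0498, but adjusted p = 0.737 with an estimated correlation). Cd5l (-1.33 ± 0.31), C1qc (-1.34 ± 0.30) and Timd4 (-1.68 ± 0.40) fell. The list was not called without LBP replicate 2 (camera adjusted p = 0.0827), although its median log2 was -0.99 against -1.02 with that library and 8 members passed over all genes. Sinusoidal endothelial markers rose in 5 of 14 (5 adjusted over the list alone; camera adjusted p = 0.0071, but adjusted p = 0.485 with an estimated correlation). They included the scavenger receptors Stab2 (2.23 ± 0.26) and Stab1 (2.00 ± 0.21), Ptprb (1.75 ± 0.23) and Kdr (1.37 ± 0.22), and 8 passed without LBP replicate 2. Across 11969 genes the FSTL3 fold changes rose with the exon length over which each gene was counted (Spearman rho = 0.458, genes not being independent replicates).

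Protein folding, mitochondrial and ribosomal genes were also lower after FSTL3. None of the settings tried removed the rise of fold change with exon length given above (Spearman rho = 0.458). The FSTL3 lists here and above were therefore not tested apart from exon length. Heat shock genes fell in 10 of 13 (12 adjusted over the list alone; camera adjusted p = 0.0025, but adjusted p = 0.649 with an estimated correlation), such as Hsph1 (log2 -2.05 ± 0.37), Hspe1 (-1.48 ± 0.23) and Bag3 (-1.57 ± 0.35). Hspa1b (-3.54 ± 0.75), which shares reads with Hspa1a, did not pass without vehicle replicate 2. Chaperones of the endoplasmic reticulum fell in 8 of 15 and rose in 1 (the same adjusted over the list alone; camera adjusted p = 0.0143, but adjusted p = 0.697 with an estimated correlation). Calr stood at -1.2 ± 0.20, Manf at -1.96 ± 0.39 and Creld2 at -2.51 ± 0.47. All 7 measured genes encoded in mitochondria fell (7 adjusted over the list alone; camera adjusted p = 1.16e-10, but adjusted p = 0.0844 with an estimated correlation). They included mt-Nd2 (14296 ± 2921 to 1107 ± 137 CPM; log2 -3.69 ± 0.27). Nuclear genes of oxidative phosphorylation fell in 17 of 34 (17 adjusted over the list alone; camera adjusted p = 2.87e-05, but adjusted p = 0.485 with an estimated correlation). On leaving out LBP replicate 2, 29 passed. Those that fell with all libraries included Cox6b1 (-1.25 ± 0.23), Cox6c (-1.16 ± 0.19) and Ndufv2 (-1.12 ± 0.15). Against the vehicle of batch 1, Cox6c (0.19) and Hspe1 (0.04) had the opposite sign, and neither these nor Cox6b1 (-0.46) and Ndufv2 (-0.21) passed. Ribosomal protein genes, many of which have pseudogene copies, fell in 35 of 65 (35 adjusted over the list alone; camera adjusted p = 8.62e-10, but adjusted p = 0.299 with an estimated correlation). Rps25 (-2.73 ± 0.31) and Rpl35a (-1.79 ± 0.16) were among them, and 46 passed without LBP replicate 2. In the same libraries, mitochondrial RNA other than the protein-coding genes took 5.07% to 10.1% of counts against 0.817% to 1.56% in vehicle, and small structural RNAs were high as given above. In the activin, TGF-beta and BMP list, which FSTL3 concerns as an activin-binding protein, 3 of 19 genes rose and 2 fell (the same adjusted over the list alone; camera adjusted p = 0.695, its median and mean positive and its test negative). Smad7, an inhibitor of that signalling, rose by 1.46 ± 0.28 and Inhbc, an activin subunit gene of hepatocytes, fell by 1.98 (SE 0.21).

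FCN2 was followed by fewer and smaller differences: 97 genes passed, 19 higher and 78 lower. Tiparp, a target gene of the aryl hydrocarbon receptor (ENSMUSG00000034640, chromosome 3, 65528410 to 65555518), rose from 9.81 ± 2.25 to 24.7 ± 4.07 CPM (log2 1.32 ± 0.29, edgeR adjusted p = 0.0381) and Cycs, cytochrome c, from 15.2 ± 4.61 to 32.9 ± 5.77 CPM (1.15 ± 0.22, edgeR adjusted p = 0.0236). Lsm5, of the complex that binds U6 RNA, rose by 2.09 ± 0.41, Ccdc68 by 2.04 ± 0.47 and Dynlt3, a dynein light chain, by 0.76 ± 0.17. The zinc finger genes Zfp51 (1.05 ± 0.20), Zfp719 (1.11 ± 0.26) and Zfp995 (1.11 ± 0.23) rose as well, with Fkbp3 (0.94 ± 0.20) and Rnf138 (0.88 ± 0.21). Derl3, which acts in the degradation of misfolded proteins of the endoplasmic reticulum (ENSMUSG00000009092, chromosome 10, 75893413 to 75895941), fell from 7.57 ± 5.44 to 0.985 ± 0.353 CPM (log2 -3.08 ± 0.62, edgeR adjusted p = 0.0301), and Srm, spermidine synthase, by 1.67 (SE 0.29). Ddx54 (-1.45 ± 0.26), Mrps34 (-1.79 ± 0.40), Trmt61a (-1.83 ± 0.44), Endog (-1.60 ± 0.36), Zmiz2 (-1.58 ± 0.27), Bahcc1 (-1.62 ± 0.34), Nbeal2 (-1.49 ± 0.33) and Slc25a34 (-1.45 ± 0.28) were the other lowest genes.

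None of the 41 gene lists tested passed after FCN2 with camera (5 had an unadjusted p under 0.05, and fry called 0). In the lists fixed for naming, Scd1, the stearoyl-CoA desaturase, stood at 9283 ± 3143 against 3246 ± 918 CPM (log2 1.52 ± 0.59, edgeR adjusted p = 0.182). Mvk stood at log2 -1.14 ± 0.37, Creb3l3 at -0.74 ± 0.20, Angptl4 at -0.61 ± 0.20, Cyp8b1 at -0.60 ± 0.24 and haptoglobin (Hp) at -0.87 ± 0.44, none of them passing (edgeR adjusted p between 0.0639 and 0.314). All of these passed without LBP replicate 2, as did 2314 genes in all, 1079 higher and 1235 lower, the 97 among them. Cyp7a1 (1.23 ± 0.49), Acss2 (0.72 ± 0.28), Il1rn (1.14 ± 0.53), Ccn2 (1.21 ± 0.45) and Fst (1.82 ± 0.66) passed with neither set of libraries. With DESeq2 size factors 64 genes passed, 20 higher (31.2%, against 19.6% of the 97) and 44 lower. DESeq2 had the opposite majority, with 763 genes, 433 higher (56.7%) and 330 lower, and limma-voom called 156, 39 higher and 117 lower. The genes that passed differed in base composition. Those higher had a median GC content of 39.6% and those lower 57.6%, against 48.7% over all genes. Fold change fell with GC content across 11961 genes (Spearman rho = -0.648). Albumin took 7.48% ± 0.605 of counts against 6.52% ± 0.378 in vehicle (2-sided exact permutation p = 0.0286; 0.0952 adjusted). On leaving out FCN2 replicate 4, vehicle replicate 1 or vehicle replicate 2, edgeR called 0 genes. With the GC trend of each library removed, it called 0 with all libraries (858 at an unadjusted p under 0.05) and 165 without LBP replicate 2.

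**Figure D4:**
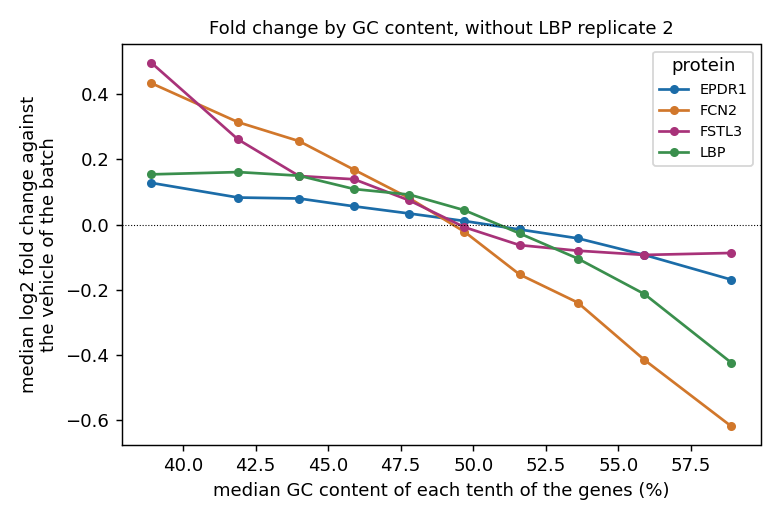
Median log2 fold change against vehicle in 10 bins of genes ordered by GC content, for each protein, without LBP replicate 2. For FCN2 the median falls from 0.43 in the bin with a median GC content of 38.9% to -0.62 in the bin with 58.9%.

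After EPDR1 no single gene passed edgeR's test (0 of 11969, 493 at an unadjusted p under 0.05, smallest adjusted p = 0.32; DESeq2 and limma-voom also called 0), and 0 passed without LBP replicate 2 (1261 at an unadjusted p under 0.05). The neutrophil chemokine Cxcl1 stood at 546 ± 233 CPM against 126 ± 133 in vehicle (log2 2.12 ± 0.62; ENSMUSG00000029380, chromosome 5, 90891241 to 90893115), Socs3, a feedback inhibitor of IL-6 signalling, at 48.8 ± 21.4 against 16 ± 11 (1.6 ± 0.42). Osmr, the oncostatin M receptor, stood at 10.2 ± 2.35 against 3.56 ± 1.97 (1.48 ± 0.41) and the antiviral gene Rsad2 at 108 ± 170 against 14.6 ± 6.49 (2.97 ± 0.76), with edgeR adjusted p of 0.937 or 0.958. Rsad2 ran from 16 to 363 CPM after EPDR1, and without EPDR1 replicate 1 its log2 was 0.75. Tiparp (1.2 ± 0.29), Tnip2 (1.23 ± 0.32), B4galt4 (1.61 ± 0.43), Sdad1 (0.58 ± 0.16) and Ppp4r4 (1.00 ± 0.27) had positive values and Arl4d (-1.15 ± 0.27), Efnb1 (-1.08 ± 0.27) and Derl3 (-2.34 ± 0.58) negative ones among the genes with the smallest p.

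Tested as lists, 6 groups passed after EPDR1, with 0 members passing over all genes in any of them, and fry called 0. Without EPDR1 replicate 1, 3 of the 6 were called, and the interferon (camera adjusted p = 0.898), immediate early (0.165) and extracellular matrix (0.109) lists were not. Without vehicle replicate 2, 3 of the 6 were called, and the interferon (camera adjusted p = 0.0944), chaperone (0.746) and extracellular matrix (0.39) lists were not. Acute phase genes were higher as a list (26 of 27 positive, 1 passing adjusted over the list alone; camera adjusted p = 7.29e-06, but adjusted p = 0.755 with an estimated correlation), such as Serpina3n (log2 0.94 ± 0.47) and Steap4 (1.07 ± 0.57, and 0.35 without EPDR1 replicate 3). Interferon response genes were higher (30 of 33 positive, 2 adjusted over the list alone; camera adjusted p = 8.51e-05, but adjusted p = 0.863 with an estimated correlation). Mx1 stood at 1.84 ± 0.53, Cmpk2 at 1.22 ± 0.42 (0.28 without EPDR1 replicate 1) and Mx2 at 0.99 ± 0.31. NF-kB and cytokine genes were higher (10 of 12 positive, 2 adjusted over the list alone; camera adjusted p = 0.00241, but adjusted p = 0.755 with an estimated correlation), with Nfkbiz at 0.76 ± 0.25 and Vcam1 at 0.76 ± 0.36. Immediate early genes (7 of 10 positive, 0 adjusted over the list alone; camera adjusted p = 0.022, but adjusted p = 0.755 with an estimated correlation) were higher, with Btg2 at 1.29 ± 0.53 and Junb at 0.84 ± 0.33. Extracellular matrix genes were higher (10 of 11 positive, 0 adjusted over the list alone; camera adjusted p = 0.0436, but adjusted p = 0.863 with an estimated correlation), such as Col1a2 (0.72 ± 0.35) and Postn (0.64 ± 0.37). They were not called without LBP replicate 2 (camera adjusted p = 0.0542), where their median log2 was 0.40 against 0.36 with that library. Chaperones of the endoplasmic reticulum were lower (13 of 15 negative, 0 adjusted over the list alone; camera adjusted p = 0.0436, but adjusted p = 0.863 with an estimated correlation), with Hyou1 at -0.77 ± 0.37 and Creld2 at -0.73 ± 0.45. Near the threshold lay the lists of glucocorticoid targets (higher, camera adjusted p = 0.0512), Kupffer cell markers (lower, 0.0518) and mitochondrially encoded genes (higher, 0.0518). Vehicle replicate 3, one of the controls, had Saa1 at 4205 CPM against 464 to 645 in the other vehicle libraries of batch 2. In simulated counts at this size and depth, edgeR called 85.1% of genes changed 4-fold and 40.5% of those changed 2-fold.

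LBP was compared with the vehicle of batch 1, 3 libraries against 4, and edgeR called 922 genes, 806 higher and 116 lower. Limma-voom called 3, edgeR on those 7 libraries alone 0 (871 at an unadjusted p under 0.05), and DESeq2 1206. Without LBP replicate 2, which leaves 2 libraries against 4, 89 passed (63 higher and 26 lower), 59 of them in both counts and in the same direction. Fold change then fell with GC content across genes (Spearman rho = -0.386). The median GC content was 45.0% in the higher genes and 60.3% in the lower ones. With the GC trend of each library removed as well, 42 genes passed. Spink1, a trypsin inhibitor of the exocrine pancreas (ENSMUSG00000024503, chromosome 18, 43728069 to 43737237), stood at 44.5 ± 50.2 CPM and at 0 in every vehicle library, at least 243-fold higher (edgeR adjusted p = 0.000911, and 0.0002 without replicate 2). Klk1, tissue kallikrein (43.6 ± 29.9 against 0.392 ± 0.713 CPM; log2 6.73 ± 0.79), Gpx3, plasma glutathione peroxidase (6.29 ± 1.00), and the neuronal noncoding RNA Bc1 (4.19 ± 0.67) rose with and without that library. Cebpb, a transcription factor of the acute phase response (ENSMUSG00000056501, chromosome 2, 167688915 to 167690418), fell from 115 ± 21.7 to 36.2 ± 5.7 CPM (log2 -1.67 ± 0.30; edgeR adjusted p = 0.00865, and 0.00437 without replicate 2), as did Fancf (-2.62 ± 0.50) and Rabep2 (-1.64 ± 0.37). Snord13 (7.52 ± 1.31), Fam25c (4.76 ± 0.85), mt-Tm (4.11 ± 0.79), Atp5k (4.05 ± 0.73), Zcchc17 (3.96 ± 0.73) and Ndufb2 (3.62 ± 0.67) rose with all libraries only. Fbxl15 (-2.64 ± 0.69), Cd180 (-2.27 ± 0.57), Rab43 (-1.90 ± 0.47), Itpr3 (-1.85 ± 0.54), Mrnip (-1.78 ± 0.54), Gpn2 (-1.73 ± 0.38) and Tert (-1.66 ± 0.39) fell with all libraries only. Pancreatic acinar markers rose in 5 of 9 (9 adjusted over the list alone; camera adjusted p = 0.00251, but adjusted p = 0.635 with an estimated correlation). Cela3b (7.64 ± 1.5), Cpa1 (5.57 ± 1.26) and Prss2 (5.41 ± 1.2) rose. Acinar genes took 0.125%, 0.002% and 0.081% of counts in LBP replicates 2, 3 and 4. In the vehicle of batch 1 they took 0.001% to 0.012%, a range that held replicate 3. The list was written for cells that may come with a piece of liver. Pancreas in some samples and an effect of LBP cannot be told apart for these markers and Spink1. Without replicate 2 the list did not pass (camera adjusted p = 0.0588) and 0 members passed over all genes, but its median log2 was 3.68 against 4.24 with that library and 9 of 9 passed adjusted over the list alone.

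Lipid synthesis genes were lower as lists after LBP. Cholesterol synthesis (2 of 25 lower, 2 adjusted over the list alone; camera adjusted p = 0.00509, but adjusted p = 0.635 with an estimated correlation) was lower. It held Dhcr7 (log2 -1.29 ± 0.34) and Srebf2 (-0.81 ± 0.25), which fell. Fatty acid synthesis (1 of 19 lower, 1 adjusted over the list alone; camera adjusted p = 0.00244, but adjusted p = 0.502 with an estimated correlation) was lower and held Srebf1, which fell from 133 ± 14.4 to 45.3 ± 34.0 CPM (-1.51 ± 0.34). Both lists passed without replicate 2 (camera adjusted p = 0.00022 and 4.08e-05), where no single member passed over all genes (3 and 5 adjusted over the list alone). In that setting fold change fell with GC content across genes (Spearman rho = -0.386). No list was tested with that trend removed. The heat shock list was higher (3 of 13, 3 adjusted over the list alone; camera adjusted p = 0.00952, but adjusted p = 0.635 with an estimated correlation). Hsp90aa1 stood at 2.59 ± 0.55, Hsp90ab1 at 1.06 ± 0.32 and Hspe1, which kept its call without replicate 2, at 1.33 ± 0.26. Ribosomal protein genes (23 of 65 higher, 34 adjusted over the list alone; camera adjusted p = 2.42e-07, but adjusted p = 0.502 with an estimated correlation) were higher. So were mitochondrially encoded genes (4 of 7, 6 adjusted over the list alone; camera adjusted p = 7.67e-05, but adjusted p = 0.502 with an estimated correlation) and nuclear oxidative phosphorylation genes (16 of 34, and 20 higher with 1 lower adjusted over the list alone; camera adjusted p = 0.00048, but adjusted p = 0.635 with an estimated correlation). Without replicate 2, edgeR called 3 of the 65, 0 of the 7 and 0 of the 34 (9, 5 and 6 adjusted over each list alone), and the ribosomal median log2 was 0.23 in place of 0.76. The ribosomal and mitochondrially encoded lists still passed without it (camera adjusted p = 0.00022 and 3.73e-06, the second with a median log2 of 0.66), and the oxidative phosphorylation list did not (camera adjusted p = 0.0785). Immediate early genes were lower (1 of 10, 1 adjusted over the list alone; camera adjusted p = 0.0446, but adjusted p = 0.502 with an estimated correlation), Zfp36 falling by 1.01 with all libraries but not passing without replicate 2. With no member passing in either count, 3 lists were lower. They were the Per and Dbp arm (12 genes; camera adjusted p = 0.0143, but adjusted p = 0.635 with an estimated correlation), bile acid and sterol transport (10 genes; camera adjusted p = 0.0122, but adjusted p = 0.635 with an estimated correlation) and CAR and PXR targets (14 genes; camera adjusted p = 0.036, but adjusted p = 0.635 with an estimated correlation). The last pair did not pass without replicate 2 (camera adjusted p = 0.62 for each). Orm1 (1.43 ± 0.41) rose and Cyp8b1 (-0.95 ± 0.26) fell with all libraries only. Mitochondrial genes took 8.55% ± 2.03 of counts against 5.32% ± 0.504 in vehicle (2-sided exact permutation p = 0.0286, the smallest that 3 against 4 allow; 0.0952 adjusted).

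The proteins were then compared with each other. Within batch 2, 5028 genes differed between EPDR1 and FSTL3 (2151 higher after EPDR1 and 2877 lower) and 5304 between FCN2 and FSTL3 (2207 and 3097). Cxcl1 stood at 546 ± 233 CPM after EPDR1 and 386 ± 94.8 after FCN2 against 4.26 ± 0.553 after FSTL3 (log2 7.0 ± 0.78 and 6.50 ± 0.76), and Saa1 at 2674 ± 967 and 1097 ± 726 against 14.7 ± 3.99 (7.51 ± 1.26 and 6.22 ± 1.19). Dmbt1, a mucosal scavenger receptor, had 1 count in all after FSTL3 and was 351-fold (61.6 to 13986) and 457-fold (80.9 to 18142) higher. Saa2 was higher by 8.01 ± 1.5 and 6.64 ± 1.42, Mup10 at least 51.4-fold after EPDR1 and Mup19 by 6.07 ± 0.63 after FCN2. Rn7sk was lower by -9.63 ± 0.49 and -10.10 ± 0.50, and Snord17, at 0 in both groups, was at least 250-fold and 308-fold lower than in FSTL3. Snora23, Scarna13 and Vaultrc5 were at least 93.4-fold, 68.3-fold and 66.6-fold lower after EPDR1, and Scarna6 and Scarna13 at least 127-fold and 84.1-fold lower after FCN2, where Rpph1, with 1 count in all, was 823-fold lower (148 to 32537). Between EPDR1 and FCN2 edgeR called 0 genes (1097 at an unadjusted p under 0.05; 71 with DESeq2, 0 with limma-voom). It called 579 without LBP replicate 2, Fcna among them (log2 0.74, edgeR adjusted p = 0.0379), and 0 when the GC trend of each library was removed as well (1401 at an unadjusted p under 0.05). Fold change between EPDR1 and FCN2 rose with GC content across 11961 genes (Spearman rho = 0.552). Responses in different batches were compared as differences of differences. LBP against FSTL3 gave 3789 genes (2002 higher and 1787 lower), with the opposite majority in limma-voom (1524 and 2240) and without LBP replicate 2 (2263 and 2362). LBP against EPDR1 gave 0 by edgeR (1605 at an unadjusted p under 0.05; 26 with DESeq2, 0 with limma-voom) and LBP against FCN2 0 (2320 at an unadjusted p under 0.05; 368 with DESeq2, 0 with limma-voom). Fcna was among the genes that differed between the LBP and FSTL3 responses (2.16 ± 0.59, edgeR adjusted p = 0.00811; 0.83 and 0.0313 without replicate 2).

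The vehicle groups of the batches differed from each other in 1456 genes, 809 higher in batch 1 and 647 lower, although neither received a protein. Dbp (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203) stood at 73.5 ± 15 CPM in batch 1 and 5.14 ± 4.86 in batch 2 (log2 4.10 ± 0.62) and Ciart was higher by 3.95 ± 0.64. Arntl (2.54 ± 1.68 against 25.4 ± 7.1 CPM; -3.31 ± 0.39) and Npas2 (1 count in all in batch 1; 40.1-fold lower, 6.97 to 1603) were lower. Mfsd2a, a lysophospholipid transporter (4.09 ± 0.61), Rgs16 (3.93 ± 0.85) and the acyl-CoA thioesterase Acot3 (3.38 ± 0.72) were higher, and Mup18 (-3.18 ± 0.69), Cyp2c69 (-3.34 ± 0.86) and the linker histone Hist1h1d (2 counts in all in batch 1; 17.4-fold, 4.62 to 146) lower. Mitochondrial genes took 5.32% ± 0.504 of counts in batch 1 and 10.5% ± 2.15 in batch 2 (2-sided exact permutation p = 0.0286; 0.0952 adjusted), and fold change rose with GC content across 11961 genes (Spearman rho = 0.509). LBP was given in batch 1 only and was compared with the vehicle of that batch. Batch and protein cannot be separated where LBP libraries are set against libraries of batch 2. That was done only with the vehicles of both batches pooled (1095 genes, 1055 higher and 40 lower). Without LBP replicate 2, 3715 genes differed between the vehicles.

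EPDR1 and FCN2 responses, which share their vehicle libraries, were correlated across genes (Pearson r = 0.516, covariance 0.116). Simulated groups with no effect against the same vehicle gave r = 0.486 (0.457 to 0.520) and a covariance of 0.052. Vehicle libraries split between the comparisons gave r = 0.158 (0.106 to 0.225). The FSTL3 responses correlated with those of EPDR1 at r = 0.097 and of FCN2 at r = 0.087, with covariances of 0.054 and 0.063 against 0.052 simulated for each pair, and at r = 0.054 for both pairs with split vehicles. FCN2 and FSTL3 shared 6 higher and 15 lower genes, and 13 were called in opposite directions. Independent lists would share 4.41 and 12.5, a value that leaves out the shared vehicle libraries. Simulated groups with no effect shared 0 in each direction, which leaves out the effects. With split vehicles, where few genes were called, means of 0 higher and 0.333 lower genes were shared against 0.138 and 0.472 for independent lists. LBP shares no controls with the others. Its responses correlated with those of EPDR1 at r = 0.087, of FCN2 at r = -0.035 (0.152 without LBP replicate 2) and of FSTL3 at r = -0.124. LBP and FSTL3 shared 32 higher genes against 187 for independent lists and 12 lower genes against 18.6, and 265 genes were called in opposite directions. Without LBP replicate 2 they shared 5 higher genes against 19.7 and 3 lower against 6.61, with 48 in opposite directions. LBP and FCN2 shared 0 higher genes against 1.28 and 10 lower against 0.756, and without that library 9 higher against 5.55 and 18 lower against 2.62. The value for independent lists ignores GC content, with which both fold changes fell without that library (Spearman rho = -0.386 for LBP and -0.636 for FCN2).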

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

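The groups of 4 libraries were searched for a single library far from the other 3, in 116 sets of values (39 of library measures and 77 of named genes), and 20 held one. Chance gives about 1 in 20 for continuous values. That rate does not hold for the sets with a share of 1.000 below, whose other values were tied at 0 or at the last printed digit. The number beside each is the gap to the nearest library as a share of the whole range, by Dixon's test for 4 values. Serum amyloid and lipocalin genes of the acute phase were high in vehicle replicate 3 of batch 2: Saa1 at 4205 against 464 to 645 CPM (0.952), Saa2 at 3051 against 164 to 305 (0.951) and Lcn2 at 146 against 14.3 to 23.3 (0.932). Other vehicle libraries of batch 2 stood apart for Endog (6.25 CPM in replicate 4 against 3.74 to 3.98; 0.901), Zfp51 (6.94 in replicate 4 against 8.69 to 8.97; 0.865) and Snord17 (0.347 in replicate 4; 0.869). For Rpph1, Snora23, Lrrtm2, Vaultrc5, Gpr21 and Scarna6 a single vehicle library was above 0 (1.000 for each). For all but Scarna6 it was replicate 2, the library with the most counts. After FCN2, Rnf138 was low in replicate 2 (24.8 CPM against 35.9 to 37.4; 0.878), and after FSTL3 replicate 4 differed for Mup4 (0.0834 against 0.521 to 0.551; 0.936) and Vmn1r13 (the single library above 0; 1.000).

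Among library measures, vehicle replicate 2 of batch 2 had 21892416 counts against at most 4038677 in the other 3 (0.921). Pancreatic acinar genes stood apart in FCN2 replicate 4 (0.002%), vehicle replicate 4 of batch 1 (0.012%) and vehicle replicate 1 of batch 2 (0.004%), and small structural RNA in vehicle replicate 2 of batch 1 (0.005% against 0.004%), each with a share of 1.000 at the last printed digit.

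Responses differed between proteins in 3789 genes for LBP and FSTL3, 5028 for EPDR1 and FSTL3 and 5304 for FCN2 and FSTL3, each by a test of the difference itself.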

How the results depend on the processing

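The settings without LBP replicate 2, without the FSTL3 libraries, with the GC trend removed, with protein-coding nuclear genes alone and with the vehicle of batch 1 as the control of FSTL3 were chosen after the data were seen, and the others before. The cause of a change was not tested. For FCN2, where 97 genes were called, DESeq2 gave 763, limma-voom 156, DESeq2 size factors 64, no filter 9, only the libraries compared 1409 and pooled vehicles 2256. It gave 2314 without LBP replicate 2, 1808 without that library and the FSTL3 libraries, 0 with the GC trend removed (edgeR; 858 at an unadjusted p under 0.05) and 165 with both that removal and LBP replicate 2 left out. For LBP (922), limma-voom gave 3, no filter 404, only the libraries compared 0 (edgeR; 871 at an unadjusted p under 0.05), the setting without the FSTL3 libraries and LBP replicate 2 gave 19, and GC removal without LBP replicate 2 gave 42. For FSTL3 (4695), no filter gave 7190, only the libraries compared 7929, and GC removal without LBP replicate 2 gave 7062. EPDR1 had 2 genes with only the libraries compared. The vehicles (1456) gave 659 with no filter, 3962 with only their libraries, 3715 without LBP replicate 2, 3291 without the FSTL3 libraries too, 716 with the GC trend removed and 2678 with that and LBP replicate 2 left out.

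Between EPDR1 and FCN2 (0) DESeq2 gave 71, the setting without LBP replicate 2 gave 579, that without the FSTL3 libraries too gave 318, and GC removal without LBP replicate 2 gave 0 (edgeR; 1401 at an unadjusted p under 0.05). For LBP against EPDR1 (0) DESeq2 gave 26, no filter 1 and GC removal without LBP replicate 2 gave 1. For LBP against FCN2 (0) these were 368, 1 and 4, and 2 without the FSTL3 libraries and LBP replicate 2. With the correlation estimated per list, camera called 0 lists for EPDR1 (6), FSTL3 (14) and LBP (11). That correlation was estimated with all libraries, LBP replicate 2 included. Fry called 0 lists for EPDR1, 4 for LBP and 18 for FSTL3, which held all 14 in the same direction. For FCN2 (0) camera called 1 without LBP replicate 2. The correlation of EPDR1 and FCN2 responses was 0.158 with split vehicles in place of 0.516, and that of LBP and FCN2 was 0.152 without LBP replicate 2 in place of -0.035.

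Samples share a replicate number and no stated pairing. A block for that number gave 51 genes for FCN2, 11 for LBP, 3 for LBP against FCN2 and 10 lists for EPDR1. Of 24 pairs of libraries of batch 2 with the same number, 9 correlated at over 0.1 (-0.129 to 0.31, median 0.0585), as did 11 of 72 with different numbers (-0.263 to 0.25, median -0.0215), and none of 3 in batch 1 did against 1 of 9. The block was not run for the vehicles of different batches, which cannot be blocked, and vehicles were pooled only where a vehicle was compared.

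Leaving out 1 library gave 0 to 95 genes for FCN2: 0 without FCN2 replicate 4, vehicle replicate 1 or vehicle replicate 2, 14 without FCN2 replicate 2, 24 without vehicle replicate 3, 25 without FCN2 replicate 1 and 46 without FCN2 replicate 3. LBP had 89 (without its replicate 2) to 2145 (without its replicate 3), with 1946 without replicate 4 and 350, 432, 289 and 331 without vehicle replicates 1, 2, 3 and 4. EPDR1 had 0 to 1 (1 without vehicle replicate 3), FSTL3 3853 to 4267 and the vehicles 857 to 1227, with 868 and 857 without replicates 3 and 4 of batch 1 and 925 and 921 without those of batch 2. LBP against EPDR1 ranged from 0 to 869 (869 and 862 without LBP replicates 3 and 4), and LBP against FCN2 from 0 to 1668 (1440 and 1668 without the same, 7 without LBP replicate 2, 3 without vehicle replicate 4). Lists called were 5 to 10 for EPDR1 (10 without its replicate 3; of the 6, 3 without its replicate 1 and 3 without vehicle replicate 2), 0 to 2 for FCN2 (1 without FCN2 replicate 1, 1 without FCN2 replicate 2, 2 without vehicle replicate 2, 1 without vehicle replicate 4), 11 to 14 for FSTL3 and 6 to 13 for LBP (6 without LBP replicate 4, 7 without vehicle replicate 3).

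With the vehicle of batch 1 as the control of FSTL3, and then also without LBP replicate 2, 10 named genes changed sign in log2 fold change: Npas2 (1.56 and 1.56), Arntl (0.43 and 0.47), Elovl3 (0.34 and 0.35), Cox6c (0.19 and 0.18), Hspe1 (0.042 and 0.006), Baat (0.029 and 0.026), Ciart (-0.039 and -0.065), Srebf1 (-0.14 and -0.13), Acot3 (-0.31 and -0.32) and Per1 (-0.65 and -0.65, edgeR adjusted p = 0.0172 in the last). Of 1381 values of 179 called named genes with 1 library left out, 1170 kept direction and call and 211 lost the call; under the other settings 1874 of 2240 kept both, 346 lost the call and 20 changed sign. Of the 31 called lists, 194 of 235 values kept the call with 1 library left out, and 147 of 204 under the other settings.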

Other observations

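The tests of small structural RNA in the FSTL3 libraries, those of the clock genes other than that of depth, and that of depth for FCN2 were chosen after the results were seen. What the splits of samples, the other tests for FCN2 and the depth test of the clock genes would show was written before each was run. The settings without LBP replicate 2 and with the GC trend removed, on which some of these rest, were chosen after other results were seen. Some gene lists passed only without LBP replicate 2. After LBP, antigen presentation genes (median log2 -0.40 over 15 genes; camera adjusted p = 0.00251, and 0.0527 with all libraries) and sinusoidal endothelial markers (-0.29 over 14; camera adjusted p = 0.00177, and 0.131) were lower, and chaperones of the endoplasmic reticulum were higher (0.35 over 15; camera adjusted p = 0.0095, and 0.189). In these 3 lists 0 members passed over all genes without that library by edgeR (0, 2 and 1 adjusted over each list alone). With all libraries, camera gave adjusted p = 0.635, 0.635 and 0.748 with an estimated correlation. Mitochondrially encoded genes were higher after FCN2 (0.48, 5 of 7 passing; camera adjusted p = 0.033, and 0.113 with all libraries) and after EPDR1 (0.28, 0 of 7 passing; camera adjusted p = 0.0134, and 0.0518). With all libraries and an estimated correlation, camera gave adjusted p = 0.968 and 0.863 for them. Without LBP replicate 2, fold change fell with GC content after FCN2 (Spearman rho = -0.636), EPDR1 (-0.282) and LBP (-0.386). The tenth of genes with the lowest GC content had a median log2 of 0.43 after FCN2. No list was tested with the GC trend removed, so these lists were not tested apart from it.

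Small structural RNAs were high in the FSTL3 libraries. Deeper sequencing is argued against by the deepest library of another group, which had 0.006% of its counts in them. A library preparation that kept RNA without a poly(A) tail stays open. The median log2 ratio of 33 histone genes was 1.74 (23 higher and 10 lower), which met the condition first set for this explanation. The most abundant histone genes in vehicle were lower (Hist1h2bc -1.43, Hist1h1c -1.55). Histone genes took 0.02% to 0.024% of counts against 0.021% to 0.03% in vehicle. That this share should be higher too was added as a condition only after the median was seen. Long noncoding RNAs and mitochondrial RNA other than protein-coding genes were also high, as given above. An effect of the protein given cannot be told apart from such a preparation, because all 4 FSTL3 libraries and no other lay above every library of the other groups. Sequencing of RNA from the same livers with a single preparation would separate them.

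The clock arms of the FSTL3 libraries differed by 4.05 on the log2 scale (1.99 and -2.05). A library preparation that kept RNA without a poly(A) tail is argued against only as far as it moves clock genes like others of the same expression. Of 10000 random pairs of protein-coding lists matched on expression, 0 differed as much (largest 2.67). Their genes were drawn singly and were not matched on exon length, with which the FSTL3 fold changes rose. Deeper sequencing is argued against by the arm difference of -0.256 in the deepest other library. A different clock time at collection was not tested apart from the pattern itself, which is that 4 of 4 FSTL3 libraries lay above every other library of batch 2. It and an effect of the protein given stay open and cannot be told apart: the 4 vehicle libraries of batch 1, with no protein, also lay above every vehicle library of batch 2. Recorded times of collection would test this.

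The FCN2 differences followed GC content. GC content bias is a candidate explanation: without LBP replicate 2 fold change fell with GC content (Spearman rho = -0.636 across genes, which are not independent replicates), and the number of calls with the GC trend of each library removed was 7.1% of that without the removal. A difference in depth is argued against by a ratio of median total counts of 1.242 with overlapping ranges. An effect of the protein given stays open: 165 genes were called with the trend removed and LBP replicate 2 left out, 28 of them among the 97 and in the same direction. It cannot be told apart from the bias, because a response in genes of high or low GC content would be removed as well.

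The libraries were also split in every other way into groups of the same sizes, or, for the differences of differences, in 100 ways drawn at random from 2450, the real one included. The real split gave more genes than every other split for FSTL3 (4695 genes, highest other 0), FCN2 (97, highest other 1) and FCN2 without LBP replicate 2 (2314, highest other 536). It did so too for the vehicles (1456, highest other 0) and for the vehicles without LBP replicate 2 (3715, highest other 203). In each, the real split alone was as large, 1 of 35. The same holds for EPDR1 against FSTL3 (5028, highest other 1; 1 of 35), FCN2 against FSTL3 (5304, highest other 1; 1 of 35) and LBP against FSTL3 (3789, highest other 3281; 1 of 100). In the last, the 5 other splits that kept FSTL3 and vehicle apart gave 1467 to 3281 genes and the remaining 94 gave 0. That result therefore rests on the FSTL3 libraries and not on those of LBP. A share of 1 of 35 is the smallest that these splits allow, and the shares were not adjusted over the comparisons. They argue against chance in these comparisons but do not exclude it. For LBP against FSTL3 the share bears on the FSTL3 libraries only and not on the LBP response. For FCN2, leaving out FCN2 replicate 4, vehicle replicate 1 or vehicle replicate 2 gave 0 genes, as given above. For LBP, 4 of 35 splits were as large (922, highest other 1060), so chance stays open. Splits with LBP replicate 2 in the group of 3 gave 334 to 1060 genes. Those with it in the other group gave 0 to 3. The count thus depended on that library, whichever libraries were grouped with it. Without LBP replicate 2 there are too few splits (15) for a share under 0.05 (89, highest other 60; 1 of 15). With edgeR counts of 0, every split was as large for EPDR1 (highest other 1; 35 of 35), EPDR1 against FCN2 (highest other 1; 35 of 35), LBP against EPDR1 (highest other 0; 100 of 100) and LBP against FCN2 (highest other 14; 100 of 100).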
